A study of Homo sapiens with 42 samples.

How the data were processed

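RNA was extracted with a QIAcube from formalin-fixed, paraffin-embedded human aortic tissue and made into libraries with the TruSeq RNA Exome kit, which captures coding sequence with probes, per the labels' protocols. Such RNA is broken into short fragments, and probes set which transcripts are seen, so levels of different genes are not compared with each other. The authors deposited 1 table of counts, with 26475 gene symbols in rows and 42 libraries in columns, of which 22 are labelled aortitis and 20 control. All its values are whole numbers of at least 0 and the library totals differ, so they were treated as counts that had not been normalized. GRCh38 is given as the genome build, and DESeq2 1.34.0 and limma 3.50.3 as tools, per the submitters' processing notes, which give no role for either tool. The aligner, the counting program, its use of strand, the gene annotation and any adjustment before deposit are not given in the sources used here. Reads shared by near-identical genes, such as HBA1 and HBA2 or HSPA1A and HSPA1B, could have been split in a way that is not known, so the values of such genes are uncertain.

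Total counts ran from 30114779 to 105299344 per library, with a median of 41771946. PCR duplicates cannot be told from the table, so depth sets only a lower bound on the error of low counts. Gene positions come from the GENCODE 29 annotation of GRCh38, where 92.7% of the symbols matched, 23851 by name and 697 through an older symbol. The table has 0 symbols of mitochondrially encoded genes, 0 of immunoglobulin segments and 0 of T cell receptor segments, so these were not analysed here. Genes on chromosome Y, XIST and TSIX are not reported. No 2 libraries held the same values within sampling noise. Over the 861 pairs of libraries the chi-square per degree of freedom, computed on genes with at least 20 counts in the pair, was never below 72.3.

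All comparisons and alternatives were chosen before the data were examined, except where the text says otherwise. The labels state separate patients by group and give no batch. Differential expression used R 4.3.3 and edgeR 4.0.16. TMM factors were computed after the filterByExpr filter on the 2 groups, which left 15373 genes. Group was tested with the robust quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of F. CPM were computed by edgeR with TMM factors, and log2 CPM used a prior count of 2. Of 50 gene lists, 47 had at least 4 tested members and were tested with camera in limma 3.58.1, with a preset inter-gene correlation of 0.01, beside camera with a correlation estimated per list and fry. Camera compares the genes of a list with all other genes. Fry asks whether the genes of a list move, on balance, one way. The score of a list in a library is the mean log2 CPM of its tested members.

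Within-library ratios of 20 gene pairs were compared on log2(count + 0.5), the SD of 10 list scores was compared between groups, and 14 relations were computed within each group, never over both. These used two-sided permutation tests with 100000 resamples, whose smallest possible p is 1e-05, and Benjamini-Hochberg adjustment over the family.

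Genes named in the text come from 3 sets. The first holds the 10 largest increases and the 10 largest decreases among genes past the threshold with a mean log2 CPM of at least 1 and at least 70% of aortitis samples beyond the control median, leaving out receptor segments, pseudogenes, unnamed loci, XIST, TSIX and chromosome Y. Another holds the first 2 members of each list and the 2 members with the largest change past the threshold. The last holds the genes of the ratios. The text names some of these.

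The tests were tried on simulated counts with the real libraries' sizes and the real genes' means and dispersions. Of 200 changed genes among 15282 tested in the simulated aortitis and control libraries, the test recovered 52% of those changed 1.5-fold, 90% of those changed 2-fold and 100% of those changed 3-fold or 4-fold, and it called 9 unchanged genes. Camera with the preset correlation called the raised list and 0 of 49 unchanged lists. The simulated genes were independent of each other, so this says nothing of lists whose genes vary together. Only 200 genes were changed, while 51.4% of tested genes were called in the real comparison. The shares recovered and the false calls may therefore differ there.

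Alternatives were DESeq2 size factors, other filters, the DESeq2 1.42.0 Wald test, limma voom with sample quality weights, a Wilcoxon rank sum test per gene, library size or surrogate variables (sva 3.50.0) as covariates, a replicate block, and leaving out each library. Added after seeing the data were a fit without the 2 libraries that stand apart on principal components and a fit with an offset for gene length and GC content, which were known for 98.4% of the tested genes.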

Results

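Gene expression was measured by RNA sequencing in human ascending aortic tissue from 22 patients with aortitis, an inflammation of the aortic wall, and from 20 disease control patients. The title of the series names CD4 T cells in giant cell arteritis, a disease in which T cells and macrophages enter the walls of large arteries. The comparison asks which genes differ between inflamed and control aortas. Total counts per library averaged 46922408 ± 15855178 in aortitis (SD, n = 22) and 44988793 ± 15529726 in controls (SD, n = 20). Log2 totals did not differ detectably between the groups (permutation p = 0.588, two-sided). The 50 most counted genes took 24.98% ± 1.38 of the counts in aortitis (SD, n = 22) and 25.79% ± 1.03 in controls (SD, n = 20), a difference of -0.806 points (permutation p = 0.0399, two-sided).

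Inflamed and control aortas differed over a large part of the measured genes. Of 15373 genes tested, 4130 were higher and 3778 lower in aortitis (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05), and 1466 were higher and 566 lower by at least 2-fold. The first principal component of log2 CPM carried 26.3% of the variance and parted the groups, with aortitis libraries from -116.9 to -10.14 and controls from 0.981 to 72.24. With an offset for gene length and GC content, an alternative added after seeing the data, 3314 genes were higher and 5083 lower, so that 39.5% of called genes were higher in place of 52.2%. Of the genes called without the offset, 6875 were called in the same direction and 0 in the other. The offset moved the median log2 fold change of all genes from 0.01 to -0.08. Without the 2 libraries that stand apart on later components, aortitis replicates 20 and 25, 4113 genes were higher and 3809 lower.

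Of the 47 gene lists tested by camera with a preset correlation, 22 ranked higher and 4 lower in aortitis. That count has a limit that applies to every list below. With a correlation estimated from the data 0 lists passed, the lowest adjusted p being 0.084, although 18 had an unadjusted p under 0.05, and fry called 30 higher and 6 lower. When the 42 libraries were split at random into groups of the same sizes, the preset correlation called a median of 8 lists per split. The descriptions therefore rest on the members of each list and on the scores per library. Member counts stand against 51.4% of all tested genes called, and members that vary together are not independent. Besides the separations given below, scores above every control were fewer for type I interferon (1 of 22 aortitis libraries), chemokine (7), giant cell (10) and CD4 memory genes (11). Scores below every control numbered 10 for TGF-beta and 2 for immediate early genes. Counts of members adjusted over the list alone equalled the counts over all genes except where stated.

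The T cell score was higher in every aortitis library than in any control. All 12 tested members of the T cell list rose, also when adjusted over the list alone, with a median log2 fold change of 2.19 (camera adjusted p = 6.64e-09; adjusted p = 0.084 with an estimated correlation). CD3E, a chain of the T cell receptor complex on chromosome 11 (118304545 to 118316175), averaged 54.8 ± 28.9 CPM in aortitis (SD, n = 22) and 11.8 ± 6.62 CPM in controls (SD, n = 20), a log2 fold change of 2.21 ± 0.24 (SE; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 2.65e-10), and was above the control median in 22 of 22 aortitis libraries. CD4, the coreceptor of helper T cells that macrophages also carry, rose by 1.66 ± 0.14 on the log2 scale (SE), and CD8A, the coreceptor of cytotoxic T cells, by 2.06 ± 0.25 (SE). T cell scores averaged 3.41 ± 0.60 in aortitis (SD, n = 22) and 1.25 ± 0.75 in controls (SD, n = 20). In all, 22 of 22 aortitis libraries lay above the highest control.

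Genes in the lists of several T cell states were higher too. Bulk tissue does not show which cells expressed them, so these rises are not assigned to T cells. In the cytotoxic list 10 of 11 members rose, including GZMB, a granzyme that kills target cells, with a log2 fold change of 3.17 (camera adjusted p = 1.61e-05; adjusted p = 0.089 with an estimated correlation). All 5 tested members of the Th1 list rose (camera adjusted p = 0.00103; adjusted p = 0.084 with an estimated correlation). Among them were STAT4 (2.84-fold) and TBX21 (2.43-fold), the transcription factor that defines Th1 cells, the latter near the floor at under 2 CPM. IFNG of that list was below the filter, with a median count of 8.5 in aortitis and 2.5 in controls. All 4 tested members of the Th17 list rose, with IL23R, a receptor chain for interleukin 23, at a log2 fold change of 3.29 and CCL20 at 3.63, or 4.41 without control replicate 18, both near the floor at under 2 CPM (camera adjusted p = 0.00211; adjusted p = 0.084 with an estimated correlation). The cytokine genes IL17A and IL17F, named after their values were seen, had a median count of 0 in both groups and were below the filter. Of the 9 genes of memory and stem-like CD4 cells, 6 rose and 2 fell (camera adjusted p = 0.0206; adjusted p = 0.36 with an estimated correlation). The risers included TCF7 (2.13), a transcription factor of stem-like T cells, and IL7R (2.45). Per CD3E within a library, TCF7 differed by -0.12 without passing (permutation p = 0.625, adjusted p = 0.677). Of the 9 inhibitory checkpoint genes 7 rose, or 8 adjusted over the list alone, led by BTLA at 2.78 (camera adjusted p = 0.000341; adjusted p = 0.084 with an estimated correlation). PDCD1, the checkpoint receptor PD-1, had a log2 fold change of 0.62, above the control median in 18 of 22 libraries, and did not pass (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.239). In the follicular helper list 4 of 7 members rose, with CXCL13 at 4.55, or 5.48 without control replicate 10, and ICOS at 2.29 (camera adjusted p = 0.0362; adjusted p = 0.14 with an estimated correlation), and that call was also lost among genes with a mean log2 CPM of at least 1 (adjusted p = 0.34, with 1.94e-09 to 0.34 over 8 alternatives). For regulatory T cells 3 of 5 tested members rose, including IL2RA (1.77) and CTLA4 (1.89), and the list did not pass by camera (adjusted p = 0.0878) while fry called it (adjusted p = 2.26e-08). FOXP3, the transcription factor of these cells, was below the filter, with a median count of 22.5 in aortitis and 3 in controls.

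B cell and plasma cell genes showed the largest list medians. All 11 tested B cell genes rose, with a median log2 fold change of 3.74 (camera adjusted p = 1.98e-09; adjusted p = 0.084 with an estimated correlation). MS4A1, the B cell surface protein CD20 on chromosome 11 (60455752 to 60470760), averaged 70.1 ± 49.8 CPM in aortitis (SD, n = 22) and 5.24 ± 6.70 CPM in controls (SD, n = 20), 13.3-fold higher (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.38e-08) and above the control median in 22 of 22. The complement receptor CR2 rose by 4.46 on the log2 scale, or by 5.78 without control replicate 10. All 8 tested plasma cell genes rose, with MZB1, a chaperone of antibody secretion, at 4.32 and FCRL5 at 4.73 (camera adjusted p = 6.28e-09; adjusted p = 0.084 with an estimated correlation). B cell scores were above every control in 21 of 22 aortitis libraries and plasma cell scores in 22 of 22. In the list of lymphoid aggregate genes 5 of 6 tested members rose, including the chemokine CCL19 at 1.87 (camera adjusted p = 0.00103; adjusted p = 0.125 with an estimated correlation).

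**Figure D1:**
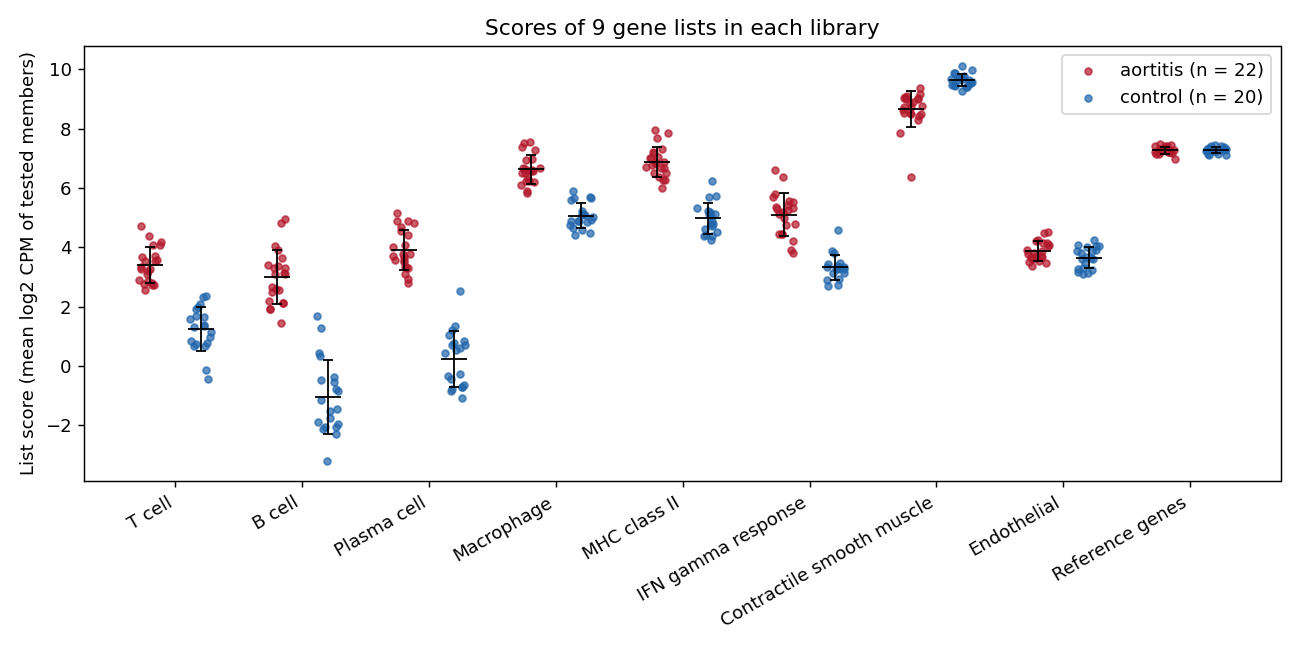
Scores of 9 gene lists, each the mean log2 CPM of its tested members (vertical axis), in the 22 aortitis and 20 control libraries; points are libraries and bars are the mean ± SD. T cell and plasma cell scores of all 22 aortitis libraries lie above every control, while smooth muscle scores of 21 lie below every control.

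Macrophage genes were higher as a group. All 14 macrophage genes rose, with a median log2 fold change of 1.42 (camera adjusted p = 7.23e-11; adjusted p = 0.084 with an estimated correlation), and 20 of 22 aortitis libraries scored above every control. CD68, a lysosomal protein of macrophages, averaged 222 ± 101 CPM in aortitis (SD, n = 22) and 83.6 ± 32.2 CPM in controls (SD, n = 20). The scavenger receptor MARCO showed the largest change of the list at 3.08. Of 9 tested genes of giant cells and osteoclasts, multinucleated cells that macrophages form by fusion, 8 rose, with SPP1 at 3.71, MMP9 at 2.97 and the fusion gene DCSTAMP 11.3-fold higher, near the floor at under 2 CPM and past the low count filter in 25 of the 42 fits that leave out a library (camera adjusted p = 0.000238; adjusted p = 0.125 with an estimated correlation). Members of the giant cell list below the filter were named after their values were seen. Of these, OCSTAMP and TM4SF19 had a median count of 0 in both groups, and ATP6V0D2 26 in aortitis and 0 in controls. Dendritic cell genes rose in 9 of 9 cases, from CD1C at 0.93 to LAMP3 at 3.36 (camera adjusted p = 0.000875; adjusted p = 0.084 with an estimated correlation). In the matrix protease list 11 of 16 members rose and 1 fell, with the macrophage elastase MMP12 at 4.52, or 5.78 without control replicate 14 (camera adjusted p = 0.000238; adjusted p = 0.089 with an estimated correlation). MMP2 was at -0.18 and did not pass, and passed with the length and GC offset (-0.27, adjusted p = 0.0363, with 0.0363 to 0.447 over 12 alternatives).

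Interferon-gamma response and antigen presentation genes rose in every tested member. They included 13 of 13 interferon-gamma genes, led by the chemokine CXCL9 at a log2 fold change of 3.64 ± 0.43 (SE) (camera adjusted p = 1.44e-08; adjusted p = 0.089 with an estimated correlation). They also included 9 of 9 MHC class II genes (camera adjusted p = 5.87e-09; adjusted p = 0.084 with an estimated correlation) and 10 of 10 MHC class I genes (camera adjusted p = 2.32e-07; adjusted p = 0.084 with an estimated correlation). HLA-DRA, which presents peptides to CD4 T cells, averaged 751 ± 299 CPM in aortitis (SD, n = 22) and 186 ± 79.1 CPM in controls (SD, n = 20). Type I interferon genes had 9 of 15 higher, a median of 0.54 and ISG15 at -0.51 without passing (camera adjusted p = 0.00958; adjusted p = 0.55 with an estimated correlation). Inflammatory cytokine genes rose in 5 of 5 tested cases, including IL1B at 1.99 and IL18 at 2.36 (camera adjusted p = 0.000263; adjusted p = 0.084 with an estimated correlation). Complement genes rose in 9 of 10 cases and fell in 1, with C2 at 1.86 (camera adjusted p = 0.000291; adjusted p = 0.117 with an estimated correlation). Chemokine genes rose in 7 of 12 cases and fell in 1, with CCL5 at 1.78 (camera adjusted p = 0.0235; adjusted p = 0.32 with an estimated correlation). Proliferation genes rose in 10 of 12 cases, with MKI67 at 1.89 (camera adjusted p = 8.12e-05; adjusted p = 0.125 with an estimated correlation). IL6 had a log2 fold change of 0.08 ± 0.38 (SE), was above the control median in 16 of 22 libraries and did not pass (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.885). In its signalling list 4 of 10 tested genes rose, among them JAK3 at 2.07 and the receptor gene IL6R at 1.12. That list did not pass by camera (adjusted p = 0.0774) while fry called it (adjusted p = 1.37e-06).

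Smooth muscle genes of the aortic wall were lower. Of 13 contractile genes 12 fell, or 13 adjusted over the list alone, with a median log2 fold change of -0.88 (camera adjusted p = 2.4e-06; adjusted p = 0.19 with an estimated correlation), and 21 of 22 aortitis libraries scored below every control. MYH11, the smooth muscle myosin heavy chain on chromosome 16 (15703172 to 15857033), averaged 10860 ± 3790 CPM in aortitis (SD, n = 22) and 22380 ± 4000 CPM in controls (SD, n = 20), a log2 fold change of -1.04 ± 0.16 (SE; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 3.82e-07), and was below the control median in 22 of 22 libraries. ACTA2, smooth muscle actin, was at -0.59 and MYOCD, a coactivator of contractile genes, at -2.00. Elastic fibre genes fell in 6 of 10 cases and rose in 2, with LTBP4 at -1.66 and FBLN5 at -1.22, while FBN1 rose by 0.45 (camera adjusted p = 0.0181; adjusted p = 0.34 with an estimated correlation). ELN, elastin itself, was at -0.29 without passing. It passed by rank sum test and without aortitis replicate 8 (-0.38, adjusted p = 0.0277), with an adjusted p from 0.0188 to 0.613 over 12 alternatives. The elastic fibre list call was also lost with the length and GC offset (adjusted p = 0.0797, with 6.77e-06 to 0.337 over 8 alternatives). Genes of the TGF-beta list fell in 7 of 11 cases, with LTBP2 at -1.18 and TGFB2 at -0.99 (camera adjusted p = 0.00751; adjusted p = 0.21 with an estimated correlation). Immediate early and stress genes fell in 6 of 10 cases, with EGR1 at -0.65 (camera adjusted p = 0.0235; adjusted p = 0.48 with an estimated correlation). EGR1 passed in 11 of 12 alternatives, with an adjusted p from 0.00172 to 0.0978. Collagen genes rose in 9 of 13 cases and fell in 2, with COL1A1 at 0.87, COL3A1 at 0.82 and POSTN at 1.81, and the list did not pass (camera adjusted p = 0.0875). It passed by fry (adjusted p = 0.00286) and with the length and GC offset (adjusted p = 0.0264), with 0.00286 to 0.609 over 8 alternatives.

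Lists of other wall cells and of blood did not pass by camera, while fry called the endothelial (adjusted p = 0.0237), activated endothelium (adjusted p = 2.87e-06) and red cell lists (adjusted p = 0.012). Endothelial genes had a median log2 fold change of 0.23, with 4 of 11 higher and 1 lower, and adventitial fibroblast genes a median of 0.06, with 1 of 8 higher and 1 lower, or 0 lower adjusted over the list alone (camera adjusted p = 0.269 and 0.757). Activated endothelium genes rose in 4 of 9 cases, among them the adhesion molecules VCAM1 at 1.27 and ICAM1 at 1.15 (camera adjusted p = 0.107). Adipocyte genes had a median of -0.825, with 2 of 8 lower, or 0 adjusted over the list alone (camera adjusted p = 0.475). For Schwann cells the median was 0.41 and the mean 0.36 while camera gave the lower direction. For platelets the median was -0.04 and the mean 0.30 while camera gave the higher direction. Neither passed (camera adjusted p = 0.54 and 0.968). Red cell genes fell in 5 of 5 tested cases with a median of -2.01, and the list did not pass (camera adjusted p = 0.116). Without control replicate 18, 3 of 5 fell and the median was -1.18. The 10 reference genes had a median of -0.02, with 1 higher and 3 lower (camera adjusted p = 0.642).

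The other lists did not pass by camera, while fry called the mast cell (adjusted p = 0.0142), mesothelial (adjusted p = 0.0116), proteoglycan (adjusted p = 0.0401) and oxidative phosphorylation lists (adjusted p = 0.0188). Mast cell genes rose in 3 of 7 cases (camera adjusted p = 0.342), lymphatic endothelial genes in 1 of 6 (camera adjusted p = 0.723) and proteoglycan and cartilage genes in 4 of 11, with 2 lower (camera adjusted p = 0.502). Glucocorticoid response genes had 2 of 8 higher and 4 lower (camera adjusted p = 0.545). Glycolysis genes had 3 of 12 higher, or 4 adjusted over the list alone, and 5 lower (camera adjusted p = 0.545). Oxidative phosphorylation genes had 1 of 13 higher and 4 lower (camera adjusted p = 0.12), and the list passed with the length and GC offset (adjusted p = 0.0209, with 0.0188 to 0.644 over 8 alternatives). Notch genes had 2 of 10 higher and 4 lower (camera adjusted p = 0.531). Schwann cell genes rose in 1 of 7 cases, and platelet genes in 1 of 4, or 0 adjusted over the list alone. Of the Th2 list 2 of 3 tested genes rose, and of the cardiomyocyte list 1 of 3 tested genes fell, which was too few members for a list test.

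Among genes chosen by size alone, the largest increases held RASSF6 (33.2-fold), DCC (27.9-fold, or 55.5-fold without control replicate 12) and ADAMDEC1 (27.2-fold, or 18-fold without aortitis replicate 1), a protease made by tissue macrophages. DCC, a netrin receptor, averaged 50.5 ± 46.2 CPM in aortitis (SD, n = 22) and 1.85 ± 4.52 CPM in controls (SD, n = 20), so that its control SD exceeded its mean. It was above the control median in 22 of 22 libraries. Among the largest decreases were CARTPT, a neuropeptide precursor, PLD5, DNER, CPAMD8 and IL31RA. PLD5 fell by 3.95 ± 0.31 on the log2 scale (SE), with mean CPM of 2.91 in aortitis and 45.0 in controls, and was below the control median in 22 of 22 libraries (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.47e-13). CARTPT averaged 0.257 ± 0.479 CPM in aortitis (SD, n = 22) and 46.9 ± 74.1 CPM in controls (SD, n = 20), with a control SD above the mean as well. Its log2 fold change was -7.54. In limma voom with quality weights it was -6.16 and did not pass (adjusted p = 0.101, with 5.28e-20 to 0.101 over 12 alternatives).

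Ratios within a library compare the balance of 2 genes between the groups without normalization, and 8 of 20 passed (two-sided permutation tests, Benjamini-Hochberg adjustment over the 20). MS4A1 per CD3E was higher in aortitis by 2.19 on the log2 scale, with means of 0.18 ± 0.81 (SD, n = 22) and -2.01 ± 1.36 (SD, n = 20) (permutation p = 1e-05, the smallest possible; adjusted p = 1e-04). CD68 per CD3E had a difference of -0.89 (permutation p = 0.00065, adjusted p = 0.00217) and CD4 per CD3E of -0.61 (permutation p = 0.0044, adjusted p = 0.011). CD8A per CD4 was higher by 0.49 without passing (permutation p = 0.0439, adjusted p = 0.0975). Macrophages also carry CD4, so the ratios that hold it do not give the share of CD4 T cells. MMP9 per CD68 was higher by 1.65 (permutation p = 8e-05, adjusted p = 4e-04). TBX21 per CD3E had a difference of -1.21 (permutation p = 0.00062, adjusted p = 0.00217), and PDCD1 per CD3E of -1.41 (permutation p = 0.00365, adjusted p = 0.0104), the latter on median counts near the floor, 15.5 in aortitis and 9.5 in controls. With the replicate block these differences were -0.997 and -1.3, and neither passed a permutation test (adjusted p = 0.0657 and 0.095). In the wall, ACTA2 per MYH11 was higher in aortitis by 0.52 (permutation p = 1e-05, adjusted p = 1e-04) and ELN per MYH11 by 0.80 (permutation p = 6e-05, adjusted p = 4e-04). COL1A1 per COL3A1 differed by 0.06 without passing (permutation p = 0.643, adjusted p = 0.677).

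Differences between patients of a group were compared over 10 lists, and 0 passed a permutation test of the SD ratio. The smooth muscle score had the widest ratio, with an SD of 0.61 in aortitis (n = 22) and 0.22 in controls (n = 20) (permutation p = 0.0372, adjusted p = 0.274). That ratio of 2.85 was 1.64 without aortitis replicate 1, whose removal gave an aortitis SD of 0.35.

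Of 28 relations between scores within groups, 12 passed by Pearson's r, and 4 did without the 2 libraries farthest on the measure named first. In aortitis libraries the T cell score ran against the smooth muscle score, with r = -0.73 (permutation p = 5e-05, adjusted p = 0.00035) and rho = -0.65 (permutation p = 0.00129, adjusted p = 0.00722). Without the 2 libraries farthest in T cell score r was -0.57 and no longer passed (adjusted p = 0.0504). In controls the same relation had r = -0.13 (permutation p = 0.598, adjusted p = 0.728) and rho = 0.02 (permutation p = 0.946, adjusted p = 0.946), with r = 0.03 without the 2 farthest libraries. Whether the relation differs between the groups was not tested. Macrophage and giant cell scores rose together in aortitis, with r = 0.86 (permutation p = 1e-05, adjusted p = 0.00028), rho = 0.78 (permutation p = 4e-05, adjusted p = 0.000373) and r = 0.79 without the 2 farthest libraries. In controls the same scores had r = 0.62 (permutation p = 0.00269, adjusted p = 0.00941) and rho = 0.48 (permutation p = 0.035, adjusted p = 0.0875). Without the 2 farthest control libraries r was 0.40 and did not pass (adjusted p = 0.231). T cell and B cell scores had r = 0.66 in aortitis (permutation p = 0.00081, adjusted p = 0.00324) and rho = 0.56 (permutation p = 0.00751, adjusted p = 0.03). Without the 2 farthest libraries r was 0.44 and no longer passed (adjusted p = 0.146). That call therefore depends on keeping those libraries, though leaving them out also tests fewer samples. In controls T cell and B cell scores had r = 0.74 (permutation p = 0.00014, adjusted p = 0.000784), rho = 0.82 (permutation p = 4e-05, adjusted p = 0.000373) and r = 0.66 without the 2 farthest.

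**Figure D2:**
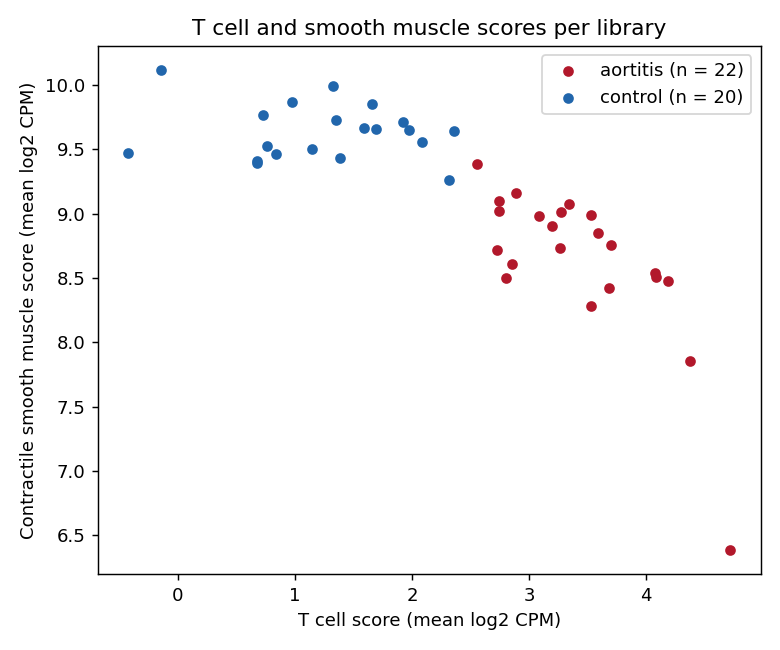
T cell score (horizontal axis) against contractile smooth muscle score (vertical axis), both as mean log2 CPM, with 1 point per library for 22 aortitis and 20 control libraries. Within aortitis r is -0.73, and within controls -0.13.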

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

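The alternatives without the 2 libraries that stand apart and with the length and GC offset were chosen after seeing the data. Over 12 alternatives genes higher numbered 3314 to 4918 and genes lower 3360 to 5083, and 6817 to 7871 of the 7908 called genes were called in the same direction, with 0 called in the other. Leaving out each library in turn gave 3987 to 4185 higher and 3643 to 3838 lower, and 1382 to 1535 higher and 520 to 598 lower by at least 2-fold. Without a low count filter 2372 genes were higher and 1019 lower by at least 2-fold, and with a mean log2 CPM of at least 1 there were 942 higher by at least 2-fold. These follow from testing more genes (21789) or fewer (12551). Lists called by camera dropped to 0 higher and 0 lower with an estimated correlation. Relations past the threshold dropped to 4 without the 2 farthest samples, which also tests fewer samples.

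The values gave no sign that the 17 numbers shared by the groups pair the samples. In these, 0 pairs had a correlation of deviations over 0.1, and the median was -0.015. The control of the same number was the best match for 0 aortitis samples. Controls matched to patients need not correlate in this way, so a matched design is not ruled out. With the replicate block on these 34 samples 3719 genes were higher and 3360 lower, against 4006 and 3519 without it. The block gave 23 lists higher and 3 lower, and 6 ratios passed. Elastic fibre (adjusted p = 0.0522) and the ratios TBX21 per CD3E (adjusted p = 0.0657) and PDCD1 per CD3E (adjusted p = 0.095) did not pass with it, nor did CD1C, CCL18, PLIN1, HBB and HBA1 among named genes, while the collagen list passed (adjusted p = 0.0453).

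Direction turned in values that had not passed, and the cause was not tested. ADIPOQ was at 0.20 with voom, MSLN at -0.00402 with surrogate variables, and IL6 at -0.02409 without the 2 libraries that stand apart and at -0.06143 with the offset. The Notch list had an adjusted p of 0.987 with the offset. With a pseudocount of 2, FOXP3 per CD3E was at -0.165, CXCR5 per CD3E at -0.183 and GZMK per CD8A at -0.00895, while IFNG per CD3E then passed at -1.08. Relations of smooth muscle in controls without the 2 farthest samples were 0.0335 with T cells, 0.0959 with macrophages, -0.105 with elastic fibre and 0.0893 with adipocytes, the last 0.0126 with DESeq2 size factors and 0.00931 given library size. In aortitis smooth muscle with adipocytes was -0.0104. PLIN1 passed in 17 of the 42 fits that leave out a library. No library lay under the minimum total planned for removal, so that alternative gave no value. Genes with a median count under 10 are limited by depth.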

Other observations

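Single genes of lists that did not pass by camera, or that had too few members for a list test, also differed. RYR2, a calcium release channel, fell by 1.30 on the log2 scale in aortitis. NCAM1, an adhesion molecule of the natural killer list, fell by 2.03 while KLRD1 of that list was higher by 1.19 (edgeR quasi-likelihood, Benjamini-Hochberg). The natural killer list had 3 of 7 members higher, or 4 adjusted over the list alone, and 1 lower, and did not pass (camera adjusted p = 0.643). LUM, a small proteoglycan, was higher by 1.73 and OGN fell by 1.07. KRT18, a keratin in the mesothelial list, was higher by 2.27, while MSLN of that list was at 0.64 without passing (camera adjusted p = 0.288 for the list, which fry called with adjusted p = 0.0116). S100A8 and S100A9, of the neutrophil list, were higher by 0.71 and 0.73, the former lost with the length and GC offset (adjusted p = 0.0636, with 0.000266 to 0.0636 over 12 alternatives), and the list had 2 of 8 members higher (camera adjusted p = 0.417).

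The tests on smooth muscle, red cell genes and the library standing apart were chosen only after the results were seen. Of 100 splits of the 42 libraries, the real one included, 1 called as many genes as the real split, with 7908 genes against at most 1787 in any other. A share of 1 in 100 is the smallest these splits can give, so chance is unlikely for that count but not excluded. For lists called with the preset correlation, 4 of 100 splits called as many as the real 26 and the highest other split called 29. That share is under 0.05, but another split called more lists than the real one and 96 of the 99 other splits called at least 1, so the count of lists is not read as evidence here. A single list call with the preset correlation can arise from libraries that vary together.

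Of 3 technical explanations for lower smooth muscle genes, the first is uniform dilution of the wall by infiltrating cells. It would lower the 26 endothelial, adventitial and Schwann cell genes alike, but their median was 0.201, against -0.884 for smooth muscle. Its 95% bootstrap interval of 0.0186 to 0.406, like those below, resampled genes and not patients. Such an interval holds no variation between patients and takes genes that vary together as independent. Schwann cell scores were lower in most aortitis libraries, with group medians differing by -0.445. Without the Schwann cell genes the median of the other 19 was 0.127 (95% bootstrap interval -4.9e-05 to 0.309). Adipocyte genes, which are not among the 26, had a median of -0.825, though their list did not pass (camera adjusted p = 0.475). A shift of the normalization away from the reference genes would lower them, and their median was -0.0198 (95% bootstrap interval -0.148 to 0.159). With the length and GC offset the smooth muscle median was -0.87 (camera adjusted p = 2.82e-05). These values argue against a shift away from the reference genes and against length or GC content as the whole cause. TMM sets the bulk of genes near 0, with a median of 0.013 over all tested genes. Genes measured from that centre cannot show whether it is right, so that question is not settled. For dilution, endothelial and adventitial genes as sets did not fall with smooth muscle, while Schwann cell scores and adipocyte genes were lower. Within aortitis the smooth muscle score also ran against the T cell score (r = -0.73) and the macrophage score (r = -0.57), as dilution would give. Without the 2 farthest libraries r was -0.57 and -0.41, and neither passed. In controls r was -0.13 and -0.02. Dilution is therefore not settled. Whether there are fewer smooth muscle cells or less expression in each, and whether new vessels offset a dilution of endothelial genes, cannot be settled from bulk tissue and stays open, as does any difference between the patients that the labels do not give.

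Red cell genes were lower in aortitis in 5 of 5 tested cases with a median of -2.01, and without control replicate 18 in 3 of 5 with a median of -1.18, so the size rests in large part on that library. A few blood-rich control libraries would leave the group medians close, but the medians of the red cell score differed by -1.27 and the means by -1.35 (permutation p of the ranks = 0.0104), and leaving out each library in turn gave medians differing by -1.31 to -1.24 (permutation p of the ranks 0.0031 to 0.0186). Less blood of every kind would lower neutrophil and platelet genes too, but the 6 and 4 of these above the floor had a median of -0.044, though inflamed tissue may bring neutrophils of its own. HBB was at -0.97 without control replicate 18 and did not pass with surrogate variables (-0.80, adjusted p = 0.146, with 0.000718 to 0.203 over 12 alternatives). How tissue was taken and rinsed is not recorded in the labels used here and stays open.

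Aortitis replicate 20 stood apart on the second principal component, at 130.9 where the next library was at 23.57. A candidate explanation is few distinct RNA molecules in that library: thinned to the total of the smallest library it had 15396 genes with a count, the fewest of the 42 libraries, where the next had 15883 and the others averaged 16818 ± 515 (SD). A few genes taking most of the counts would raise the share of the 50 most counted genes, which was 26.1% and inside the range of the others, 22.5% to 27.3%. No biological explanation was tested.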
